A study of Mus musculus with 2 samples.

How the data were processed

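B16 F10 is a mouse melanoma line that makes melanin. Per the labels' protocols, cells were seeded at 100 cells per cm2 in high-glucose DMEM with 10% fetal bovine serum, trypsinised on day 7, and sorted on a flow cytometer by side scatter, which was the measure of pigment. The low pigment and the high pigment fraction each gave 1 library made with the 10x Genomics single cell 3' v3.1 kit. This kit tags the 3' end of polyadenylated RNA in droplets and marks each molecule with a unique molecular identifier (UMI). Each library is the only replicate of its group, so cells were not treated as replicates and no test between groups was made.

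The count matrix holds UMI counts per gene and barcode as the authors deposited it, made with Cell Ranger 6.1.2 on build mm10 per the submitters' processing notes, with both libraries aggregated. Whether the aggregation step equalised depth between the libraries, and how reads matching several genes were counted, is not given in the sources used here. Ribosomal protein genes, Gapdh, Fth1, the metallothioneins and the class I genes have close copies, and their counts are uncertain to that extent. The authors also deposited a cell table, whose columns give UMI counts and genes per cell, the percent of UMIs from mitochondrially encoded and from ribosomal protein genes, scores per cell for gene sets, a cell cycle phase and a cluster number. The gene sets behind the authors' deposited scores are not given in the sources used here. The matrix held 5818 barcodes and 32285 genes, and 4036 cells were in the authors' table. These were exactly the barcodes with at least 7500 UMIs and under 10% mitochondrial UMIs, with 0 exceptions. UMIs per cell in the table and the matrix differed by at most 17. The table names the sort of each cell, and the library number of the barcode matched that name in all 4036 cells. No column of values without a known sample was used.

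Counts were summed over the table's cells per library and scaled by the library's total UMIs to CPM. The ratio of high pigment to low pigment CPM was given with an exact conditional binomial 95% interval, and each CPM with an exact Poisson 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals cover counting error only and leave out differences between cultures, sorts and library preparations. Those of CPM and ratios also leave out variation from cell to cell within a library. A gene counted as measured with a mean CPM of at least 10, and genes were counted at 1.5-fold by size alone. Among the 7849 measured genes, the smallest sum in either library was 59 UMIs, and the median gene's interval reached a factor of 1.09 to either side of its ratio. A count of 3 UMIs, taken as the limit of detection, was 0.0925 CPM in the low pigment and 0.104 CPM in the high pigment library.

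The following choices were made before the data were examined. The text names the 12 genes with the largest and the 12 with the smallest ratio among genes with a mean CPM of at least 50. It also names up to 3 members with the largest and 2 with the smallest ratio in each of 27 gene lists, of which the melanin list and the lineage transcription factor list could be given in full. The lists held 612 entries, of which 610 were found in the matrix. They covered melanin synthesis, melanosome transport, lineage transcription factors, the dedifferentiated melanoma state, S phase, G2 and M phase, glycolysis, hypoxia, oxidative phosphorylation, mitochondrially encoded genes, the unfolded protein response, ATF4 targets, p53 targets, NRF2 targets, lysosome, autophagy, cholesterol synthesis, interferon response, class I antigen presentation, extracellular matrix, immediate early genes, heat shock, ribosome biogenesis, ribosomal proteins, iron and copper, calcium, and chromatin. Some lists share members: Jun, Atf3 and Btg2 stand in the immediate early list and in another list each, and Fth1 and Ftl1 in the NRF2 and the iron lists. A member was called higher or lower at 1.25-fold by size alone. Of the 7849 measured genes, 5159 (65.7%) lay within this limit, and counts of called members are to be read against that share. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a test. Some genes that these rules pick are not reported here. Markers of fibroblasts, leukocytes, endothelial cells, keratinocytes, erythroid cells and Schwann cells were also fixed.

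Cell cycle phases were called with scanpy 1.11.5 from the S and the G2 and M lists, after thinning every cell to 7500 UMIs without replacement. No cell of the table was shallower. The share of a cell's UMIs from a list was compared on the same thinned cells. Doublets were marked per library with Scrublet as built into scanpy at an expected rate of 0.06, which marked 18 low pigment cells (0.947%) and 15 high pigment cells (0.702%). Marked cells were kept in the main values. RNA free in the droplets was not estimated. Gene coordinates, the length of the main transcript and its GC content came from GENCODE M21 on the same mouse build. Of the measured genes, 7846 matched it by gene identifier. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

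The ratio step was tested on simulated counts for 7849 genes at the depth of the libraries. These counts had Poisson error alone, so the coverage found says nothing about variation from cell to cell. For true ratios of 1.25, 1.5, 2 and 0.5 the median estimates were 1.24, 1.48, 1.98 and 0.493, with 50 genes each, and the intervals held the true value for 94% to 98% of them. Alternatives covered the scaling, the expression minimum, the cell filter, the weight of each cell, thinning, doublets, the genes in the totals, cells called G1 and the fold threshold. Removal of a transcript length trend (lowess, fraction 0.3), barcodes of at least 2000 UMIs outside the table, and the authors' phase calls were added after seeing the data.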

Results

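The data are single-cell RNA counts from B16 F10 mouse melanoma cells, which the labels call melanocytes, sorted by side scatter into a low pigment and a high pigment fraction after 7 days of growth. Each fraction gave 1 library, so no difference has a replicate check and all intervals cover counting error only. The low pigment library held 1900 cells and 32437194 UMIs, with a median of 16019.5 UMIs per cell (range 7597 to 46001) and 4215 genes per cell. The high pigment library held 2136 cells and 28848691 UMIs, with a median of 12557 UMIs per cell (range 7514 to 38940) and 3600 genes per cell. The median share of mitochondrial UMIs was 5.62% in the low pigment and 5.07% in the high pigment library.

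The comparison asks which genes differ between weakly and strongly pigmented cells of the same line. As a share of its UMIs, the high pigment library had more RNA of the melanocyte transcription factors Mitf and Sox10, of the coactivator Ppargc1a and of several melanin genes. Its share was several-fold smaller for immediate early genes such as Jun, Fos, Egr1 and Dusp1, and smaller for nearly all cholesterol synthesis genes. All ratios here compare such shares and not RNA per cell, since high pigment cells had fewer UMIs (median 12557 against 16019.5). Of the S phase genes 19 of 41 were lower, and of the G2 and M phase genes 17 of 50 were higher, in the high pigment library, with most others called neither. Of 7849 measured genes, 255 (3.25%) were at least 1.5-fold higher and 634 (8.08%) at least 1.5-fold lower in the high pigment library. The median gene had a log2 ratio of −0.08. With this median set to 0 the counts were 357 higher and 462 lower. With a minimum of 2 CPM in place of 10 they were 513 and 1360.

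Among the better expressed genes, those with the largest ratios had 2.10-fold to 2.47-fold more RNA in the high pigment library. Tnrc6a, a part of the machinery of microRNA silencing, had 56.4 CPM in the low pigment and 139 CPM in the high pigment library (2.47-fold, 2.34–2.61). Pmepa1, a feedback inhibitor of TGF-beta signalling, was 2.39-fold higher. Ppargc1a (chromosome 5, 51454250 to 51567726), a coactivator of mitochondrial biogenesis, had 101 against 234 CPM, a ratio of 2.32 (2.23–2.42). Lgals3 (chromosome 14, 47367751 to 47386160), which encodes galectin-3, had 301 against 697 CPM (2.32-fold, 2.26–2.37). Mitf (chromosome 6, 97807052 to 98021349), the central transcription factor of melanocytes, had 221 against 506 CPM (2.29-fold, 2.22–2.35). Hmox1 (chromosome 8, 75093621 to 75100589), which degrades heme, had 129 against 291 CPM (2.26-fold, 2.17–2.34). The apoptosis inhibitor Cflar (2.19-fold), Phldb3 (2.18-fold), Map7d2 (2.17-fold), the fatty acid binding protein gene Fabp7 (2.11-fold) and the actin regulator Eps8 (2.10-fold) were also in this group.

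The genes with the smallest ratios were 4.53-fold to 7.95-fold lower in the high pigment library. Dusp1 (chromosome 17, 26505590 to 26562128), a phosphatase of MAP kinases, had 169 CPM in the low pigment and 21.3 CPM in the high pigment library, 7.95-fold lower (7.31–8.65). The AP-1 genes Fosb, Jun and Fos were 6.86-fold, 6.54-fold and 6.28-fold lower, Jun (chromosome 4, 95049034 to 95052222) with 842 against 129 CPM. The kinase gene Sik1 was 5.93-fold lower, the zinc finger gene Egr1 5.85-fold, the antiproliferative gene Btg2 5.68-fold and the nuclear receptor gene Nr4a1 5.05-fold lower. Arid5a was 4.93-fold lower. Hmgcs1 (chromosome 13, 119690379 to 119708260), an early enzyme of cholesterol synthesis, had 153 against 31.0 CPM (4.92-fold lower, 4.58–5.29). The kinase gene Pim3 and the Notch target Hes1 were 4.61-fold and 4.53-fold lower. All 24 genes kept their direction and at least a 1.5-fold size in each of the alternative settings run, several of which leave gene ratios unchanged.

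**Figure D1:**
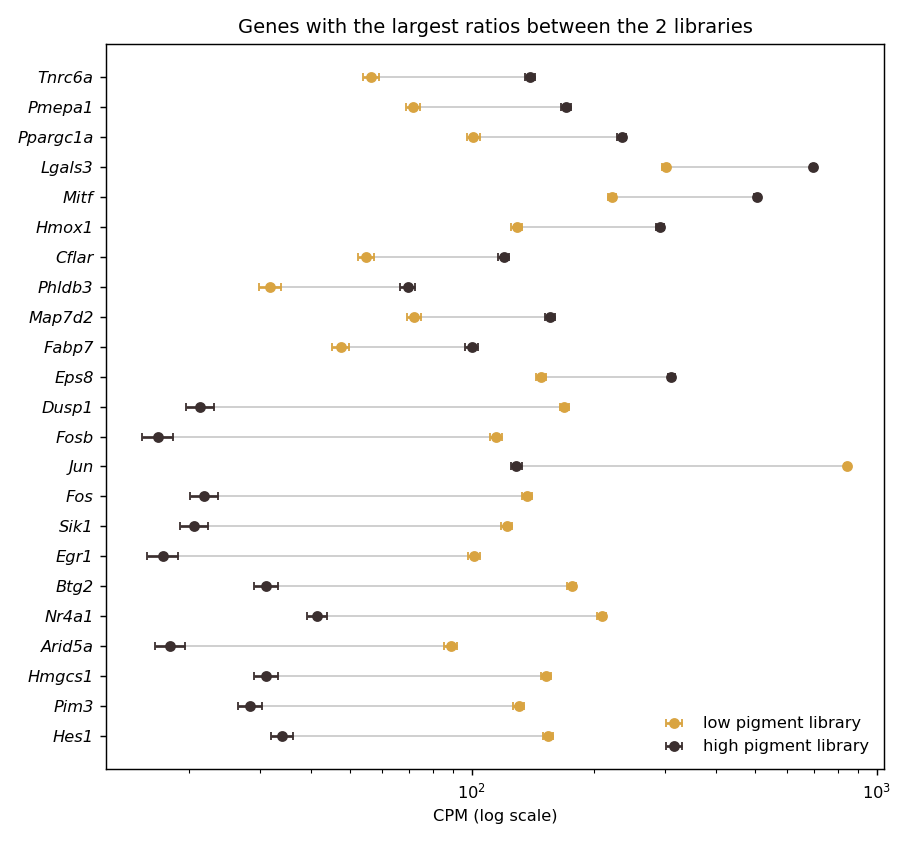
CPM (log scale) of genes with the largest and the smallest ratios in the low pigment and the high pigment library, with exact Poisson 95% intervals that cover counting error only. Jun stood at 842 in the low pigment and 129 in the high pigment library, and Mitf at 221 and 506.

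Of the 16 measured melanin and melanosome structure genes, 7 were called higher in the high pigment library by the size limit for list members, 1 was lower and 8 were neither. The median log2 ratio was 0.26, at percentile 99.7 of random lists. Ptgds, a prostaglandin synthase gene, had 1600 against 2407 CPM (log2 ratio 0.59), Tspan10 was 1.48-fold and the cystine transporter gene Slc7a11 1.45-fold higher. Mlana had 1658 against 2299 CPM (1.39-fold) and Dct, the dopachrome tautomerase, 5856 against 8011 CPM (1.37-fold, 1.36–1.38). Trpm1 was 1.33-fold higher. Cited1, a transcriptional coactivator, had a log2 ratio of 0.32, but −0.029 among cells called G1. Tyrp1 lay just under the limit, with 1832 against 2286 CPM. Slc45a2, Atp7a, Gpnmb and Gpr143 had ratios of 1.14, 1.13, 1.12 and 1.05. Tyr, which encodes the rate-limiting enzyme tyrosinase, had 126 against 122 CPM, a ratio whose interval (0.928–1.02) held 1. Slc24a5 and the fibril gene Pmel were 1.11-fold lower each, Pmel with 1432 against 1286 CPM. The melanocortin receptor gene Mc1r was 1.43-fold lower, with 39.7 against 27.7 CPM.

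The 9 measured lineage transcription factors were split, with 3 higher, 4 lower and 2 neither. Sox10 had 118 against 223 CPM (1.89-fold, 1.81–1.96) and Tfap2a 37.7 against 56.7 CPM (1.51-fold), beside Mitf. Creb1 had a ratio of 1.04, and Pax3 had 306 against 270 CPM. Sox5 was 1.29-fold, Zeb2 1.33-fold, Usf1 1.43-fold and Tfe3 1.68-fold lower. The list's median log2 ratio was −0.18 and its mean 0.06, at percentile 14.6. Among members of at least 50 CPM the median was 0.37. These were Mitf and Sox10, which were higher, and Pax3 and Zeb2, which had less RNA in the high pigment library. That median lies between Sox10 and Pax3, with no member near it. Melanosome transport genes had 3 of 20 members higher and 2 lower, with a median of 0.03 that was −0.01 among cells called G1. Mlph, which ties melanosomes to the myosin motor, was 1.75-fold higher, Bloc1s4 1.65-fold and Rab27a 1.43-fold higher, while Hps1 was 1.31-fold and Ap3m1 1.46-fold lower. Lysosome genes had 2 of 28 members higher (Atp6v1a 1.33-fold, Ctsb 1.26-fold) and 5 lower, with Ctsz 1.37-fold lower and a median of −0.10 (−0.12 to −0.024 across settings). Autophagy genes had 4 of 17 higher, led by Vps18, Map1lc3b and Atg16l1 at 1.35-fold, 1.33-fold and 1.32-fold, and 3 lower, with Wipi2 1.52-fold and the initiating kinase gene Ulk1 2.30-fold lower. Their median was 0.10 and their mean −0.01.

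Of the 17 measured immediate early genes, which are induced within minutes by growth factors and by dissociation of tissue or cultures, 15 were called lower in the high pigment library and 0 higher. The median log2 ratio was −2.34, below all 10000 random lists. The smallest differences in this list were at Klf6, Myc and Ier3, which were 1.12-fold, 1.19-fold and 1.49-fold lower. The low pigment library, where these genes were higher, also had 434 barcodes (14.5%) with over 50% mitochondrial UMIs against 5 (0.177%) in the high pigment library, all outside the cells compared. The dedifferentiated state list had 6 of 8 members lower, with Jun and Ccn1 (6.07-fold) lowest and Ccn2 1.27-fold lower, 1 higher, Sox9 (1.79-fold), and 1 neither, Tcf4 (ratio 0.849). Its median was −0.38, at percentile 0.44, and −1.10 among members of at least 50 CPM. Jun, the most abundant member, also stands in the immediate early list. Across cells this list correlated with the immediate early list at a rho of 0.659 in the low pigment and 0.474 in the high pigment library. Part of that correlation comes from Jun being in both. The lower values of this list therefore cannot be told apart from those of the immediate early genes. Heat shock genes had 5 of 10 lower, with Hspa8 at 1925 against 1037 CPM (1.86-fold lower) and Hsph1 1.53-fold lower, and none called higher, Bag3 having the largest ratio at 1.16. Their median was −0.32. Unfolded protein response genes had 9 of 20 lower and 0 higher, with a median of −0.30. The chaperone gene Hspa5 had 1130 against 725 CPM (1.56-fold lower) and Pdia6 was 1.72-fold lower, while Manf, Atf6 and Sel1l had ratios of 0.951, 0.925 and 0.878. ATF4 targets had 9 of 22 lower and 0 higher, with a median of −0.28 (−0.28 to −0.13 across settings). Atf3 was 3.80-fold and Ddit3 1.78-fold lower, and Nupr1, Psat1 and Nars had the largest ratios at 1.19, 1.18 and 1.13. Pecam1, fixed as an endothelial marker, also had less RNA in the high pigment library (726 against 81 UMIs, 7.97-fold lower, 6.33–10.2), while the other endothelial markers Cdh5, Kdr, Tek and Emcn had at most 3 UMIs in either library.

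Cholesterol synthesis genes were lower as a group. Of 20 measured members, 19 were called lower in the high pigment library, with a median log2 ratio of −0.79 that lay below all 10000 random lists. Hmgcs1 was the lowest member. The members nearest to 1 were Nsdhl (1.15-fold), Hsd17b7 (1.32-fold) and Fdps (1.40-fold lower), and among cells called G1 Hsd17b7 had a log2 ratio of 0.22.

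S phase genes had 19 of 41 members lower and 2 higher, with a median log2 ratio of −0.29 at percentile 0.02. Uhrf1, which maintains DNA methylation at replication forks, had 136 against 62.2 CPM (2.19-fold lower) and Dscc1 was 2.13-fold lower. Fen1 and Exo1 were 1.35-fold and 1.33-fold higher, and Cdca7 had a ratio of 1.16. Among cells called G1, which were chosen by these genes, the S phase median was 0.20. G2 and M phase genes had 17 of 50 members higher and 0 lower, with a median of 0.16 at percentile 99.98 (0.11 to 0.34 across settings). Gtse1 was 2.18-fold, G2e3 1.96-fold and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, 1.85-fold higher (156 against 288 CPM), while Ndc80 and Psrc1 had ratios of 0.851 and 0.804. After thinning to equal depth, 51.5% of low pigment cells (49.2–53.7) and 39.0% of high pigment cells (36.9–41.1) were called S, against 36.7% and 22.0% without thinning and 37.1% and 22.4% by the authors' calls. The share called G2M was 20.7% (18.9–22.6) in the low pigment and 39.3% (37.2–41.4) in the high pigment library, a gap of 18.6 percentage points. Cells called S or G2M together made up 72.2% (70.1–74.2) and 78.3% (76.5–80.0). Without thinning these were 65.4% and 74.0%, and 60.6% and 66.9% by the authors' deposited calls. The authors' calls placed 23.5% and 44.4% in G2M. The phase calls rest on the same lists, and the side scatter gate can set such shares. Free RNA was not estimated and stays open for calls per cell.

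**Figure D2:**
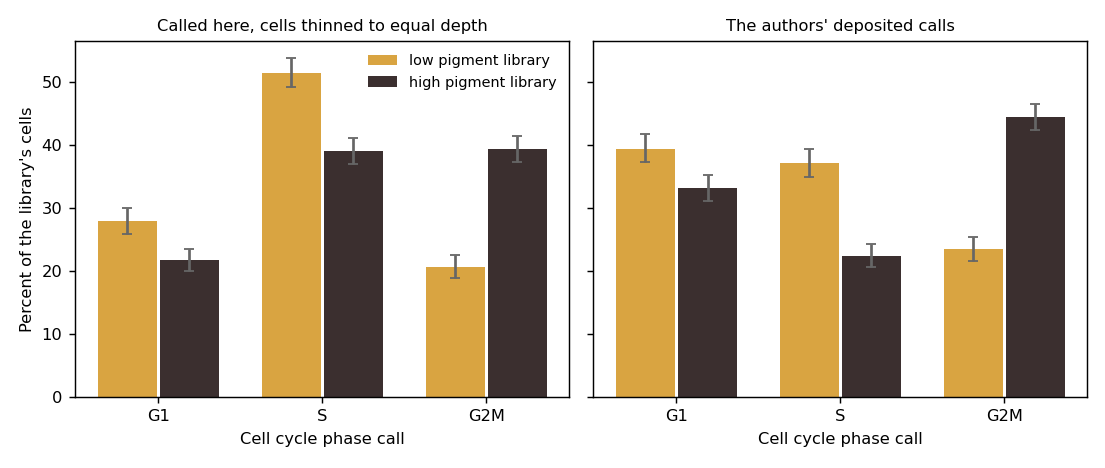
Percent of each library's cells called G1, S and G2M, from cells thinned to equal depth (left) and from the authors' deposited calls (right), with exact binomial 95% intervals that cover counting error only. The share called G2M was higher in the high pigment library in both panels, 39.3% against 20.7% on the left and 44.4% against 23.5% on the right.

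Nuclear-encoded oxidative phosphorylation genes had 8 of 38 members higher and 3 lower, with a median log2 ratio of 0.12 at percentile 87.0. Cox7a2 had 908 against 1308 CPM (1.44-fold), Atp5g1 and Ndufa2 were 1.37-fold and 1.36-fold higher, and Atp5b was 1.41-fold lower. With the length trend of all genes removed the median was −0.059. The 13 mitochondrially encoded genes had 3 members lower and 0 higher and a median of −0.24, at percentile 0.075, which ranged from −0.47 with the length trend removed to −0.16 with the median gene set to 1. mt-Atp8 was 1.61-fold and mt-Nd5 1.28-fold lower, while mt-Co2, mt-Cytb and mt-Nd4 had ratios of 0.985, 0.962 and 0.952. Cells with 10% or more mitochondrial UMIs were outside the authors' table, which bounds this list in both libraries. Glycolysis genes had 1 of 18 higher, Eno2 (1.44-fold), and 1 lower, Pfkl (1.32-fold). Hk2 and Ldha had ratios of 1.19 and 1.18, and Gapdh was 1.22-fold lower. The glycolysis median was −0.13, at percentile 10.5 (−0.15 to −0.0023 across settings). Hypoxia genes had 3 of 15 higher, Higd1a (1.66-fold), Ero1l (1.65-fold) and Bnip3 (1.41-fold), and 6 lower, with Vegfa 1.93-fold and Ddit4 2.04-fold lower. Their median was −0.17, at percentile 16.9, and 0.26 among members of at least 50 CPM.

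The p53 target list had 6 of 13 members higher and 3 lower, with a median log2 ratio of 0.25 at percentile 99.7. The cell cycle inhibitor gene Cdkn1a had 246 against 458 CPM (1.86-fold, 1.81–1.92), Eda2r was 1.66-fold and Phlda3 1.53-fold higher, while Btg2 was lowest and Gdf15 was 1.32-fold lower, but had a log2 ratio of 0.30 among cells called G1. Oxidative stress and NRF2 targets had 6 of 21 higher and 1 lower, with a median of 0.14 at percentile 93.6 (0.038 to 0.22 across settings). Besides Hmox1, the glutathione synthesis genes Gclm (240 against 480 CPM) and Gclc (1.42-fold) were higher, Gsr was 1.33-fold lower and Cat had a ratio of 0.812. Iron and copper genes had 2 of 16 higher, Atox1 (1.42-fold) and Ireb2 (1.35-fold), with Slc40a1 at a ratio of 1.23, and 4 lower, with Mt2 1.33-fold and Aco1 1.39-fold lower, though Aco1 had a log2 ratio of 0.019 among cells called G1. Their median of −0.03, at percentile 61.5, was 0.05 with the median gene set to a ratio of 1.

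Interferon response genes had 4 of 7 measured members lower and 0 higher, with a median log2 ratio of −0.51 at percentile 0.83. Among members of at least 50 CPM, which left Bst2 alone, it was −0.095, and among cells called G1 −0.29. Ifit2 was 1.78-fold lower, while Isg15, Bst2 and Ifi35 had ratios of 0.981, 0.936 and 0.875. Of 5 class I genes, H2-K1 and H2-D1 were 2.07-fold and 1.63-fold lower, and Psmb10, B2m and Tapbp had ratios of 1.01, 0.949 and 0.934, for a median of −0.10 (−0.38 to −0.018 across settings). Extracellular matrix genes had 4 of 16 higher, with Spp1 1.48-fold, Sparc 1.46-fold and Cd44 1.38-fold higher, and 3 lower, with Mcam 1.40-fold and Mmp14 1.42-fold lower. Their median of −0.04 was 0.47 among members of at least 50 CPM and 0.04 with the median gene set to 1. Calcium genes had 2 of 15 higher, S100a6 (1.66-fold) and Stim2 (1.45-fold), with S100b at a ratio of 1.24, and 4 lower, with the channel genes Orai3 (1.54-fold) and Orai1 (22.8 against 14.2 CPM) lowest. Their median was −0.08, at percentile 47.3, and 0.07 among members of at least 50 CPM. Chromatin genes had 2 of 18 higher, Hmga2 (65.3 against 125 CPM, 1.92-fold) and the acetyltransferase gene Crebbp (1.44-fold), with Ep300 at a ratio of 1.22, and 4 lower, with Kat5 1.45-fold and Hdac1 1.51-fold lower. Their median was −0.11, at percentile 15.3. It was 0.19 among members of at least 50 CPM and 0.10 among cells called G1. Ribosome biogenesis genes had 8 of 24 lower, with Nop56 1.72-fold and Polr1b 1.53-fold lower, and 1 higher, Ppan (2.73-fold), with Nme1 and Wdr43 at ratios of 1.16 and 1.13. Their median was −0.08, at percentile 14.2 and like that of all measured genes, and 0.04 among cells called G1. Ribosomal protein genes had 4 of 32 lower, with Rpl5 1.38-fold and Rpl3 1.49-fold lower, and 0 higher, Rps27 and Rpl27 having ratios of 1.22 and 1.18. Their median of −0.05 was 0.03 with the median gene set to 1 and ranged down to −0.23.

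**Figure D3:**
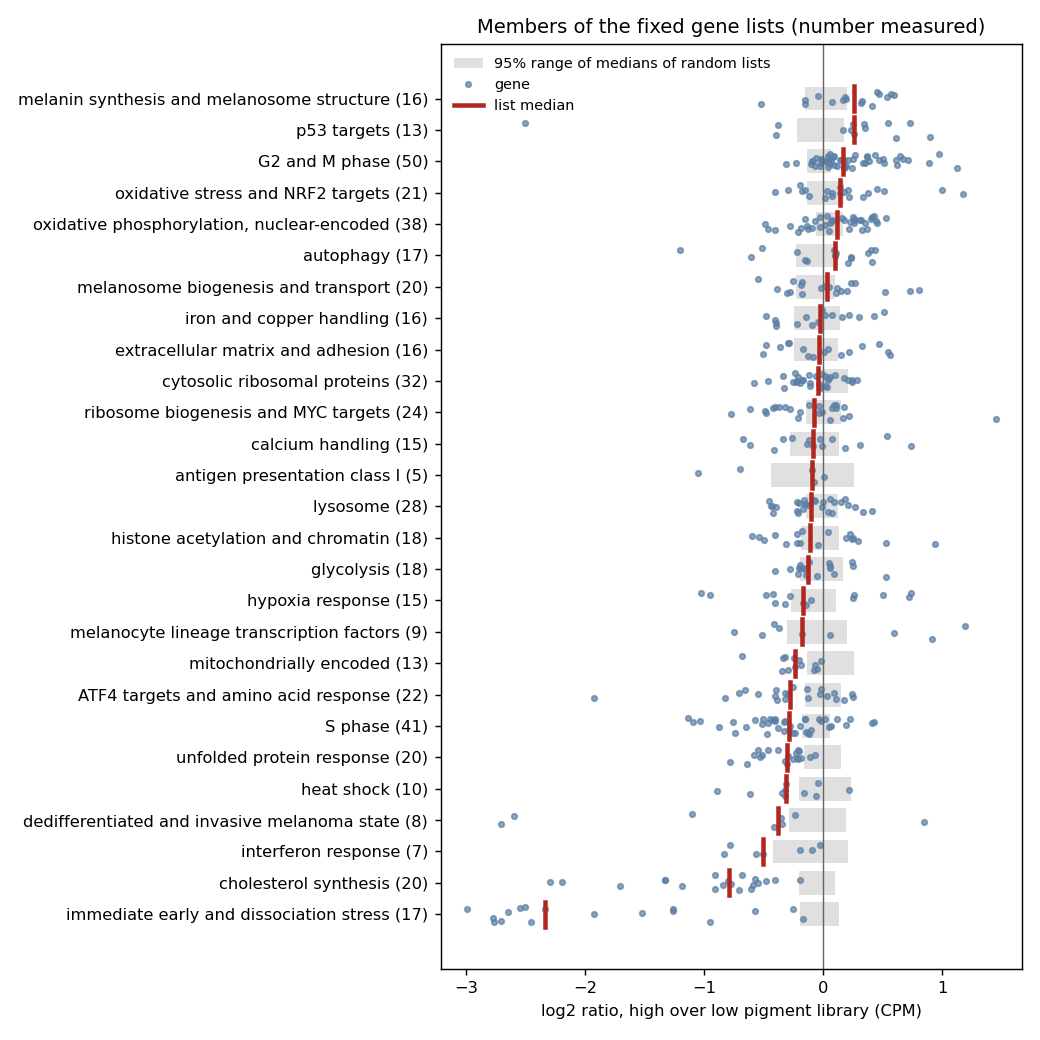
Log2 ratio of high pigment over low pigment CPM for each measured member of the 27 lists (points), the list median (bar) and the 95% range of medians of random lists matched on expression (grey). Of the 27 medians, 12 lay outside the grey range, 3 of them higher and 9 lower, with immediate early genes at −2.34 and cholesterol synthesis at −0.79.

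In individual cells, melanin genes overlapped widely and immediate early genes did not. The melanin list took a median of 1.48% of a cell's UMIs in the low pigment and 1.93% in the high pigment library, and 78.4% of high pigment cells (76.6–80.1) lay above the low pigment median, or 79.4% without thinning. Among cells called G1 this share was 75%. The summed percent of UMIs is set mostly by abundant members. Dct alone took a median of 0.587% in the low pigment and 0.773% in the high pigment library. For Dct, 72.9% of high pigment cells (71.0–74.8) lay above the low pigment median. Immediate early genes took 0.293% against 0.0667%, and 98.8% of low pigment cells (98.2–99.2) lay above the high pigment median. For cholesterol synthesis, with 0.187% against 0.0933%, 12.5% of high pigment cells (11.2–14.0) lay above the low pigment median.

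**Figure D4:**
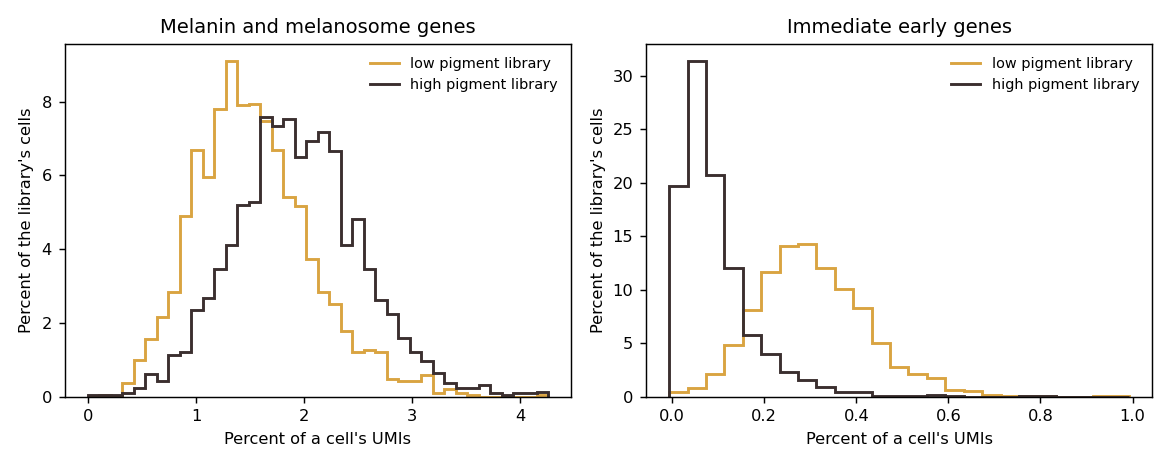
Distribution over cells of the percent of UMIs from melanin genes (left) and immediate early genes (right), as the percent of each library's cells in each bin, with cells thinned to equal depth. The medians were 1.48% and 1.93% for melanin genes and 0.293% and 0.0667% for immediate early genes, in the low pigment and the high pigment library.

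Markers of other cell types were near the limit of detection in both libraries, with exceptions. Fibroblast, keratinocyte and erythroid markers had at most 45 UMIs in a library (Col1a2 in the high pigment library). Among leukocyte markers Itgam had 87 against 4 UMIs, with at most 2 in any cell, Cd79a had 48 against 17, and Ptprc had 1 against 0. The Schwann cell markers Mbp (154 against 101 CPM, 1.54-fold lower) and S100b were abundant in both libraries, and Pmp22 had 5.06 against 4.71 CPM. The authors' deposited clusters followed the libraries: clusters 1 and 2 held 97.1% (96.2–97.8) of low pigment cells and clusters 0 and 3 held 95.6% (94.7–96.5) of high pigment cells. A cluster made mostly of cells from 1 library can be that library rather than a cell type, so cluster sizes were not compared further. Among the authors' deposited scores, hMel_StemState had a median of 0.327 in low pigment cells (SD 0.0224 across cells) and 0.298 in high pigment cells (SD 0.0220). mHFmel_StemState had 0.147 (SD 0.0429) against 0.0889 (SD 0.0430). hMel_MatState had 0.664 (SD 0.0290) against 0.677 (SD 0.0391), and mHFmel_MatState 0.283 (SD 0.0350) against 0.289 (SD 0.0335). hMel_ProState had medians of 0.501 and 0.501, and mHFmel_ProState 0.508 and 0.518.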

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

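The test on short-lived transcripts and the correlations with length within ribosomal protein and oxidative phosphorylation genes were chosen after those results had been seen. The test on transcripts of all kinds was added after the correlation over all genes was seen, but before its own values. The bounds of the other tests were set after the ratios, list medians and the authors' phase calls were known, but before the value each test measures. The low pigment library had 434 barcodes outside the cell table with over 50% mitochondrial UMIs (14.5% of its barcodes, 13.3–15.9), and the high pigment library 5 (0.177%, 0.0574–0.412), a signal in data that no comparison used. The 434 barcodes had a median of 902.5 UMIs and 75 genes.

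Immediate early genes had a median log2 ratio of −2.34 between the high pigment and the low pigment library. With cells thinned to equal depth the median was −2.17. Random thinning keeps each gene's expected share of a cell's UMIs, so this step could hardly move the median and is no test of depth. For the same reason, fewer UMIs drawn at random from each cell would not by themselves give a median of −2.34. Losses that differ between genes were not tested. Of low pigment cells, 98.8% lay above the high pigment median, so the higher share was not confined to a few low pigment droplets. RNA free in the droplets was not estimated and could spread RNA of some cells over all droplets. A subset of activated cells is therefore not excluded. Among 29 short-lived transcripts outside the list, 16 were lower, 4 higher and 9 neither, with a median of −0.47 (quartiles −1.05 and −0.07). This lies between the bounds set for and against a general loss of short-lived RNA, so that explanation cannot be told apart from the rest. The set also holds genes that stimuli can induce, such as Klf10, Maff and Nfkbia. A low median could therefore not separate a loss of short-lived RNA from lower induction. Hes1, Cflar, Cdkn1a, Txnip and possibly others of this set had been seen beforehand. A difference in handling or cell damage, of which the 434 against 5 mostly mitochondrial barcodes may be a sign, could also set these genes apart, as could pigment itself, and neither was tested because each group has 1 library.

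Short transcripts had higher ratios: outside ribosomal and oxidative phosphorylation genes, the median log2 ratio was 0.20 for transcripts under 600 nt and −0.09 for those of 1000 to 2000 nt, a difference of 0.29. Across genes, which are not independent replicates, Spearman's rho of the ratio with transcript length was −0.53 within 81 ribosomal protein genes and −0.58 within 38 oxidative phosphorylation genes, against −0.05 over all measured genes. Removing the length trend moved the oxidative phosphorylation median from 0.12 to −0.059, so a length bias between the libraries is a candidate explanation for that list. The cholesterol synthesis median was −0.79 before and −0.80 after the same step. Over all measured genes the medians of the length bins lay only between −0.12 and 0.24. Removing so small a trend could not have brought this list to the bound set for length, so that test is void. The values show only that a trend of this size is too small to make the cholesterol median. Whether the length relation comes from library preparation or from the cells stays open with 1 library per group.

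The gap in cells called G2M was 18.6 percentage points after thinning and 23.3 without it, which argues against depth as the whole cause. Without the cells marked by Scrublet the gap was again 18.6, which met the bound set beforehand against doublets. That test is void, since only 18 and 15 cells were marked, too few to make up the gap, and Scrublet cannot see doublets of like cells, so doublets cannot be told apart here. The sort itself could favour cells near division because side scatter was the gate, although high pigment cells had fewer UMIs (median 12557 against 16019.5). A link between pigment and the cell cycle is equally open. Neither was tested.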

How the results depend on the processing

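The removal of the length trend, the added barcodes and the authors' phase calls were chosen after seeing the data. All 24 genes named for their ratio kept direction and at least a 1.5-fold size in each setting of scaling, expression, cells and length that was run. Over all named and list genes, 8 of 2439 combinations of a called gene and a setting reversed. Many of these combinations could not reverse. The expression minima and the cell filter left gene ratios as they were, and changed scaling or totals shift all genes by the same factor. The low number of reversals is therefore in part built into the settings, as is the stability of the 24 genes. Among cells called G1 the log2 ratios were −0.029 for Cited1, 0.020 for Dtl, 0.45 for Rrm2, 0.077 for Chaf1b, 0.30 for Gdf15, 0.22 for Hsd17b7 and 0.019 for Aco1, and with the length trend removed Atp5e had −0.043. The S phase list reversed to 0.20 among cells called G1, which were chosen by those genes. For the other reversals the cause was not tested. The melanin median stayed positive throughout, at 0.34 with the median gene set to 1, 0.32 at a minimum of 2 CPM and 0.32 at 50 CPM, 0.23 with every cell weighing the same, 0.20 among cells called G1 and 0.20 with the length trend removed. Counts of genes at least 1.5-fold higher and lower were 513 and 1360 at 2 CPM and 78 and 117 at 50 CPM, because other numbers of genes were counted, and 52 and 160 at a 2-fold threshold. The share higher among these was 28.7% in the main values and 43.6% with the median gene set to 1, with 357 higher and 462 lower. S or G2M cells were 65.4% and 74.0% without thinning, and 60.6% and 66.9% by the authors' calls, in the low pigment and the high pigment library. The G2M gap was 23.3 points without thinning. The share of high pigment cells above the low pigment melanin median was 75% among cells called G1.

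The filter at 1000 genes and 10% mitochondrial UMIs removed no cell and so says nothing about stability. Other cluster resolutions were not run, because the authors' clusters were used. No paired analysis was possible because each group has 1 library, and no replicate could be left out for the same reason. The largest interval factor of a measured gene was 1.32. The minimum of 10 CPM in large part fixes this, so it does not show whether depth limits genes below that minimum. The intervals of CPM and ratios cover counting error only. Variation from cell to cell within a library was left out of them, and error between cultures, sorts and preparations cannot be estimated.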

Other observations

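The genes in this paragraph were chosen after their values were seen. The muscle ubiquitin ligase genes Trim63 and Fbxo32 were 3.07-fold (2.81–3.35) and 2.64-fold (2.36–2.95) higher. The gap junction gene Gja3 had 6.20 against 27.7 CPM (4.46-fold, 3.82–5.24), the placental growth factor gene Pgf was 3.22-fold, the natriuretic peptide gene Nppb 2.69-fold and Irak2 2.67-fold higher. Dicer1, which makes microRNAs, was 2.41-fold higher beside Tnrc6a. Flcn, a regulator of nutrient signalling at the lysosome, was 2.27-fold higher (26.3 against 59.6 CPM). Its partners Fnip2 and Fnip1 went in different directions, 1.34-fold higher and 1.26-fold lower, and Rragd and Rragc had ratios of 0.883 and 0.892.

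Lower in the high pigment library, again chosen after seeing the values, were Arl4d (20.7 against 2.05 CPM, 10.1-fold, 7.77–13.5), the poly(A) polymerase gene Tent5c (8.01-fold), Txnip, which restrains glucose uptake (54.6 against 7.49 CPM, 7.29-fold), and Socs3, a feedback inhibitor of cytokine signalling (6.74-fold). Slc5a3, a myo-inositol transporter induced by high osmolarity, was 3.93-fold lower with 144 against 36.7 CPM. The histone gene Hist1h2ac was 3.98-fold and Hist1h1c 1.35-fold lower. The cyclin gene Ccnf was 2.41-fold higher.

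For the hypotheses that follow, the bounds were set after the ratios were known but before the correlations were computed. The first was that the difference between the libraries follows an axis of melanin gene expression that also runs among cells within a library. Across 3034 genes, which are not independent replicates, the ratio between libraries correlated with the within-library correlation to melanin genes at Spearman's rho of 0.113 in the low pigment and 0.239 in the high pigment library. These values lie between the bounds set for and against, so the hypothesis cannot be told apart from its absence, although the within-library correlations of the libraries themselves agreed at a rho of 0.704. Mitf had within-library correlations of only 0.102 and 0.0478 with the melanin share, and Eps8 0.285 and 0.305.

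The second hypothesis was that immediate early RNA is carried in the authors' mHFmel_StemState score, which was higher in low pigment cells. Across cells within a library the score correlated with the immediate early share of UMIs at a rho of 0.574 in the low pigment and 0.602 in the high pigment library. The higher score of low pigment cells may therefore reflect the same RNA as the immediate early list in part, which its gene set, not given in the sources used here, would decide.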
